A study of Drosophila melanogaster with 8 samples.

How the data were processed

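The series profiled wing imaginal discs of *Drosophila melanogaster* larvae in the third instar by Targeted DamID. Per the labels, larvae expressed Dam-RNase H1 or Dam alone under *nub*-Gal4, grew at 25 °C and spent 24 h at 29 °C before dissection. Groups were taken from the genotype labels: control Dam-only (1 library), control Dam-RNase H1 (3), ecd1 Dam-only (1) and ecd1 Dam-RNase H1 (3), 8 libraries in all. The description of the ecd1 Dam-only library calls it a Dam-RNase H1 library while its title and genotype call it Dam-only; it was grouped by the genotype. The design text speaks of biological replicates. Per the labels' protocols, methylation-specific PCR products were sequenced as paired 50 bp reads.

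The files hold no value of a single library. Each genotype has 1 list of all peaks and 1 table with a single peak per gene, and the comparison of the genotypes is given as a table of regions higher in control and a table of regions higher in ecd1, again with a single region per gene. Regions next to no gene, and further regions of the same gene, are therefore in the difference tables only where another gene brings them in. The genome build is BDGP6, release 6 of the *Drosophila* genome, per the submitters' processing notes. The aligner, the peak caller, the handling of replicates and the way Dam-only libraries entered are not given in the sources used here, and the depth per library is unknown. The peak height deposited by the authors is a score without a stated scale or log base. It was used to describe and rank peaks within a list. Where heights of separate lists are set side by side, the lists were made separately. At the 138 regions higher in ecd1 and the 1 region higher in control whose start and end also occur in both peak lists, the height in the difference table equalled the difference of the peak heights within 0.015 in every case, so difference heights are on the scale of the peak heights and are subtractions. The FDR (a q-value) of each peak was deposited by the authors and lies under 0.01 throughout. Values from the difference tables are the authors' own comparison, and no test between genotypes was rerun on them.

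Gene identifiers of the tables were matched to a RefSeq gene table of the assembly Release 6 plus ISO1 MT, which gave gene spans and types for 10449 of 10500 identifiers (99.5%). It has no strand or exons and no genome sequence came with it, so transcription starts, untranslated regions, GC content and GATC density were not analysed here. Spreadsheet software had turned 4 symbols of the difference tables into dates; they were restored through their identifiers. The authors' tables assign regions to genes within a few kb: 99% of the matched genes lay within 4711 bp of their control peak and 4785 bp of their ecd1 peak, and 69.9% and 69.7% overlapped it.

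Overlap was counted from 1 bp on and compared with 1000 placements of the other set shuffled within chromosome arms. Midpoints of peaks were placed within 500 bp of either end of a gene span, inside a span or in neither, against 1000 shuffled placements. Gene lists were tested with two-sided Fisher exact tests among the 9826 genes with a peak in either genotype, with Benjamini-Hochberg adjustment over both directions; the direct comparison used genes with regions in 1 direction only, and occupancy was tested among all 17684 annotated genes on the 6 chromosome arms. Genes are not replicates, so these p-values describe the lists. X was compared with the autosomes by Fisher's exact test. The threshold was an adjusted p of 0.05 and shares have 95% Wilson intervals.

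The lists, named genes, tests and most alternatives were fixed before the data were examined. The 19 lists were spliceosome, Xrp1 and stress, JNK and cell death, ecdysone response, wing patterning, Hippo and growth, cell cycle and replication, DNA damage, R-loop factors, heat shock, ribosomal proteins, histones, tRNA, snRNA and snoRNA, neuron and glia, myoblast and muscle, trachea with blood cells and fat body, Polycomb and Trithorax, and genes present in the transgenes. Named are the 10 genes with the largest height in each direction with at least 5 that have more than a CG or CR number, up to 4 members per list with a differing region, the 5 genes with the tallest peaks of each genotype, and in any case *ecd*, *Prp8*, *Xrp1*, *Irbp18*, *nub*, *rnh1*, *Ilp8* and *puc*. This rule selected 99 genes, of which the text gives the leading ones. List members named without a value (such as *bsk* or *hid*) illustrate a count and were chosen after it was seen. The plan allowed for values per library; as there are none, the comparison of the genotypes rests on the authors' calls.

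Alternatives were the regions of larger height, heights of at least 1, an FDR under 0.001, regions on a called peak, merging of regions within 1000 bp, a reciprocal overlap of 50%, placement over the whole genome, only genes overlapping their peak, other backgrounds, the nearest gene of each region, logistic models with log gene length, protein-coding genes only, a 1000 bp window, any overlap in place of midpoints, and bases in place of counts. Chosen after seeing the data were the reassignment of genes by spans within 1000 bp, circular shifts, a logistic model with gene length and number of peaks, and the alternatives of the direct comparison. The tests were checked on simulated lists for the comparison of gene lists among the 9826 genes: 16 of 20 lists made with an odds ratio of 6 were called, 13 of 180 unchanged lists had p under 0.05, and the 95% intervals of the logistic model held the true ratio in 97 of 100 (no effect) and 93 of 100 (odds ratio 4) runs. Simulated genes were drawn independently, whereas in the data 1 region can stand beside several genes. The logistic lists were not drawn to the sizes of the fixed lists. The check does not cover these features of the data. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.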

Results

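Binding of RNase H1 to chromatin was mapped in wing imaginal discs of *Drosophila melanogaster* larvae in the third instar by Targeted DamID. In this assay a DNA adenine methylase (Dam) is expressed at a low level, alone or fused to the protein of interest, and the adenines it methylates in GATC sites mark the DNA that the fusion contacted. RNase H1 recognises RNA:DNA hybrids, so the Dam-RNase H1 fusion marks places where such hybrids can form. The discs came from control larvae and from larvae carrying ecd1, a temperature-sensitive allele of *ecd* (*ecdysoneless*), a gene needed for ecdysone synthesis and, with the U5 splicing factor Prp8, for pre-mRNA splicing. Larvae grew at 25 °C and were moved to 29 °C for 24 h on day 6 after egg laying, which switched on the Dam constructs under the wing driver *nub* and inactivated the mutant protein at the same time; discs were dissected on day 7. The labels give 8 libraries, namely 3 control and 3 ecd1 Dam-RNase H1 libraries and 1 Dam-only library of each genotype. The files analysed hold 1 peak list per genotype and 1 table of differing regions per direction, so no value has a replicate error, and the depth of the libraries is unknown. All p-values below describe genes or positions in these lists, not biological replicates.

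Dam-RNase H1 peaks covered largely the same parts of the genome in both genotypes. The control list held 8597 peaks over 17.8 Mb and the ecd1 list 9559 peaks over 17.4 Mb. Of the control peaks, 7181 (83.5%) overlapped an ecd1 peak by at least 1 bp, and 76.8% of the ecd1 peaks overlapped a control peak. Shuffled within their chromosome arms, ecd1 peaks met 23.9% of the control peaks on average and 25.3% at most in 1000 placements (one-sided permutation p = 0.001, the smallest these placements can give), a 3.50-fold difference. The placements ignored where GATC sites lie, which both genotypes share. Part of this excess can therefore come from the assay itself, whatever RNase H1 bound. The shared bases, 13.3 Mb, made up 74.8% of the control and 76.2% of the ecd1 peak bases. With a reciprocal overlap of 50% required, 63.9% of the control peaks and 57.5% of the ecd1 peaks were shared.

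At the level of genes, the authors' gene tables placed 8284 genes beside a control peak and 8754 beside an ecd1 peak. Both tables held 7212 of them, which was 87.1% of the control and 82.4% of the ecd1 genes, where 4101 shared genes were expected for independent lists among 17684 annotated genes. A peak in control discs only was listed for 1072 genes and a peak in ecd1 discs only for 1542. The tables list 1 peak per gene and leave out some genes near a peak. *Prp8* (FBgn0033688, 2R:12154258-12162998), which encodes the core U5 snRNP protein, stood only in the ecd1 table. Yet a control peak of height 0.64 lay 714 bp outside its span, beside an ecd1 peak of height 0.69 at 607 bp.

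The tallest peaks of each list overlapped a peak of the other list. In control discs they lay at *CG5966* (X:5992409-5993363, height 2.61), at the shared end of *CG5380*, annotated as the RNA polymerase III subunit Polr3F, and *PyK*, the pyruvate kinase gene (3R:22366814-22367680, 2.52), at *CG5466* (3R:20619801-20620265, 2.42), and inside *crc*, the ATF4 homologue (2L:21312736-21315886, 2.42). In ecd1 discs they lay at *Archease* and *CG15497* (3R:21662351-21663834, 3.89), inside *ftz-f1*, an ecdysone-regulated nuclear receptor gene, with the non-coding gene *CR45939* (3L:18786998-18787552, 3.83), and at *snoRNA:Me28S-A576* (3L:17569246-17570580, 3.54). Peak heights are the authors' scores on an unstated scale. Their median was 0.88 (quartiles 0.65 and 1.17) for control and 1.10 (0.79 and 1.5) for ecd1, with median widths of 1575 and 1378 bp. The lists were made separately. Among 1801 peaks with the same start and end in both lists, 1530 (85.0%) had the larger height in the ecd1 list, 263 in the control list and 8 had equal heights, with medians of 1.32 and 1.02. Of the tallest control peaks, the ecd1 list has a height of 1.98 at *CG5966*, 2.23 at *CG5380* and *PyK*, 3.39 at *CG5466* and 2.79 at *crc*, so the last 2 were taller in the ecd1 list. Within the *crc* control peak, however, the authors' deposited table gives a region of 0.76 as higher in control (2L:21313489-21314138). Another region, 383 bp outside *crc*, is given as 0.70 higher in ecd1 (2L:21309417-21310483). Of the tallest ecd1 peaks, the control list has 1.74 at the *Archease* and *CG15497* peak, 2.32 at *ftz-f1* and 1.82 at *snoRNA:Me28S-A576*.

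**Figure D1:**
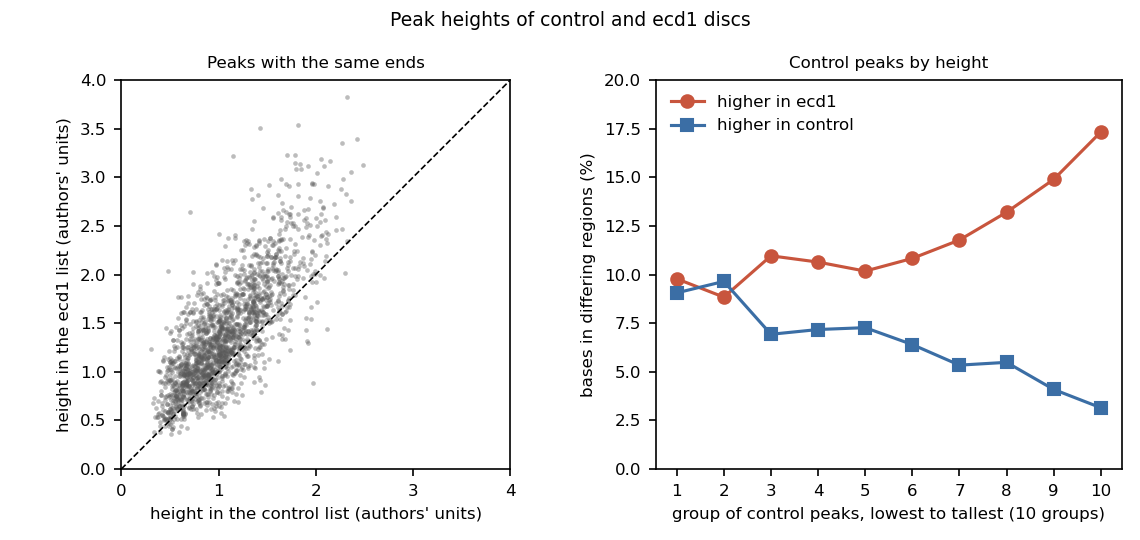
Left, heights of the 1801 peaks with the same start and end in both lists, control on the x axis and ecd1 on the y axis, in the authors' unstated units; the dashed line marks equal heights, and 85.0% of the points lie above it. Right, control peaks in 10 groups of equal number from the lowest to the tallest, with the percent of their bases in regions higher in ecd1 (circles), which was 9.78 in the lowest and 17.3 in the tallest group, and in regions higher in control (squares), which was 9.06 and 3.15.

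The central comparison asks where inactivation of ecd1 altered Dam-RNase H1 binding. By the authors' deposited table of each direction, 4083 distinct regions were higher in ecd1 and 1628 were higher in control, so that 71.5% of the 5711 differing regions were higher in ecd1 (95% Wilson interval 70.3 to 72.6, counting error only). The authors' deposited tables assign them to 6019 and 2456 genes, and 1231 genes had a region in each direction. Regions higher in ecd1 had a median height of 0.74 and those higher in control one of 0.52 in the authors' deposited tables. Among the 889 regions with a height of at least 1, 92.2% were higher in ecd1. Regions higher in ecd1 lay on ecd1 peaks in 89.5% of cases and on control peaks in 64.0%; regions higher in control lay on control peaks in 76.4% and on ecd1 peaks in 44.8%. All 4 shares exceeded the highest of 1000 shuffled placements, which was 21.4% or lower. The regions were selected for signal of the higher genotype, so their overlap with peaks of that genotype was largely fixed in advance. They were also deposited only where assigned to a gene, while the placements covered whole arms. The tables hold 1 region per gene and direction and have no values per library, so the calls could not be tested against replicate spread.

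Regions with the greatest heights on the ecd1 side lay inside or beside the genes *CG6398*, *Cda5*, *CG32982*, *bnl*, *CG31459*, *CG12581*, *N*, *kirre* and *COQ7*. In the authors' deposited table the first of these were inside *CG6398* (X:17833852-17834433, 2.40) and inside *Cda5*, a chitin deacetylase gene (2L:45262-47615, 2.40). They were followed in the authors' deposited table by *CG32982* (2L:9126691-9127521, 2.32), *bnl*, which encodes the FGF ligand Branchless, with *CG31459* (3R:19836473-19838637, 2.21), and *CG12581* (3R:4173894-4174822, 2.21). A region at one end of *N*, the Notch receptor gene, and 243 bp outside *kirre* (X:3134775-3135849) had a height of 2.16 in the authors' deposited table, and one 4622 bp from *COQ7* (X:6777661-6779042) had 2.09. The *bnl* region was an ecd1 peak of height 2.94. Several of these genes also had a region higher in control in the authors' deposited table. The heights were 0.35 for *Cda5*, 0.60 for *bnl*, 1.15 for *CG31459*, 0.66 for *CG12581*, 0.50 for *N* and 0.47 for *kirre*. None was listed for *CG6398*, *CG32982* and *COQ7*.

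On the control side the greatest heights were smaller. The authors' deposited table gives 1.89 for a region inside *hng3* and 330 bp from *emc*, a helix-loop-helix inhibitor of wing vein and bristle fate, which is also listed for *tRNA:iMet-CAT-1-3* (3L:747895-749070). Regions of 1.80 inside *plum* (3R:26507826-26508263), 1.76 inside *eIF5B*, a translation initiation factor gene (3L:3441873-3443186), 1.74 inside *Ptp61F*, a tyrosine phosphatase gene, with *SA-2* (3L:1438453-1438941), and 1.62 at *CG12895* and *Galphao* (2R:10436977-10437674) came next in the authors' deposited table. Apart from *CG12895*, each of these genes also had a region higher in ecd1 in the authors' deposited table, for *emc* one of height 1.37 inside the gene (3L:749853-751248).

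Genes named in the study's title and design were examined whatever their values. *Xrp1* (FBgn0261113, 3R:18914968-18926989), a bZIP transcription factor of the stress response, had 3 control peaks with heights of 0.59 to 0.96 and 4 ecd1 peaks with heights of 1.01 to 2.27. The authors' deposited table lists a region of height 0.93 over its right end as higher in ecd1 (3R:18922884-18927553). Its partner *Irbp18* (FBgn0036126, named *CG6272* in the files) had a region higher in ecd1 inside the gene (3L:11097666-11098152), with a height of 0.94 in the authors' deposited table. *Ilp8* (FBgn0036690, 3L:17029812-17032080) encodes the relaxin-like hormone that damaged discs release to delay pupariation. A peak over the right end of the gene (3L:17031956-17036015) had a height of 1.61 in control and 2.82 in ecd1. Most of this peak lay outside *Ilp8*, and it also covered *lncRNA:CR45756* and *lncRNA:CR43250*. The authors' deposited table places a region of 1.35, listed beside 4 genes, over the same end of *Ilp8* (3L:17031956-17032784). It gives another of 1.65 at 904 bp outside *Ilp8* (3L:17032984-17035378). *puc* (FBgn0243512, 3R:8105332-8122294), the JNK phosphatase and a target of that pathway, held regions of both directions. Inside the gene the authors' deposited tables give 1.31 higher in ecd1 (3R:8120658-8121472) next to 0.86 higher in control (3R:8119675-8120296). *nub* itself (2L:12587625-12628135) had 2 regions higher in ecd1 inside the gene, of heights 1.02 and 1.60 in the authors' deposited table. *ecd* (3L:2263581-2265857) is in none of the gene tables; a peak 152 bp outside it (3L:2262499-2263429) had heights of 0.69 in control and 1.71 in ecd1, and the authors' deposited table gives the same interval as 1.02 higher in ecd1. *Prp8* had no differing region within 1000 bp. *rnh1*, the endogenous gene of RNase H1 (2R:7931054-7932380), had a peak of height 2.22 in both lists and a region of 0.77 higher in ecd1 in the authors' deposited table (2R:7931158-7931926); the Dam fusion carries RNase H1 sequence.

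**Figure D2:**
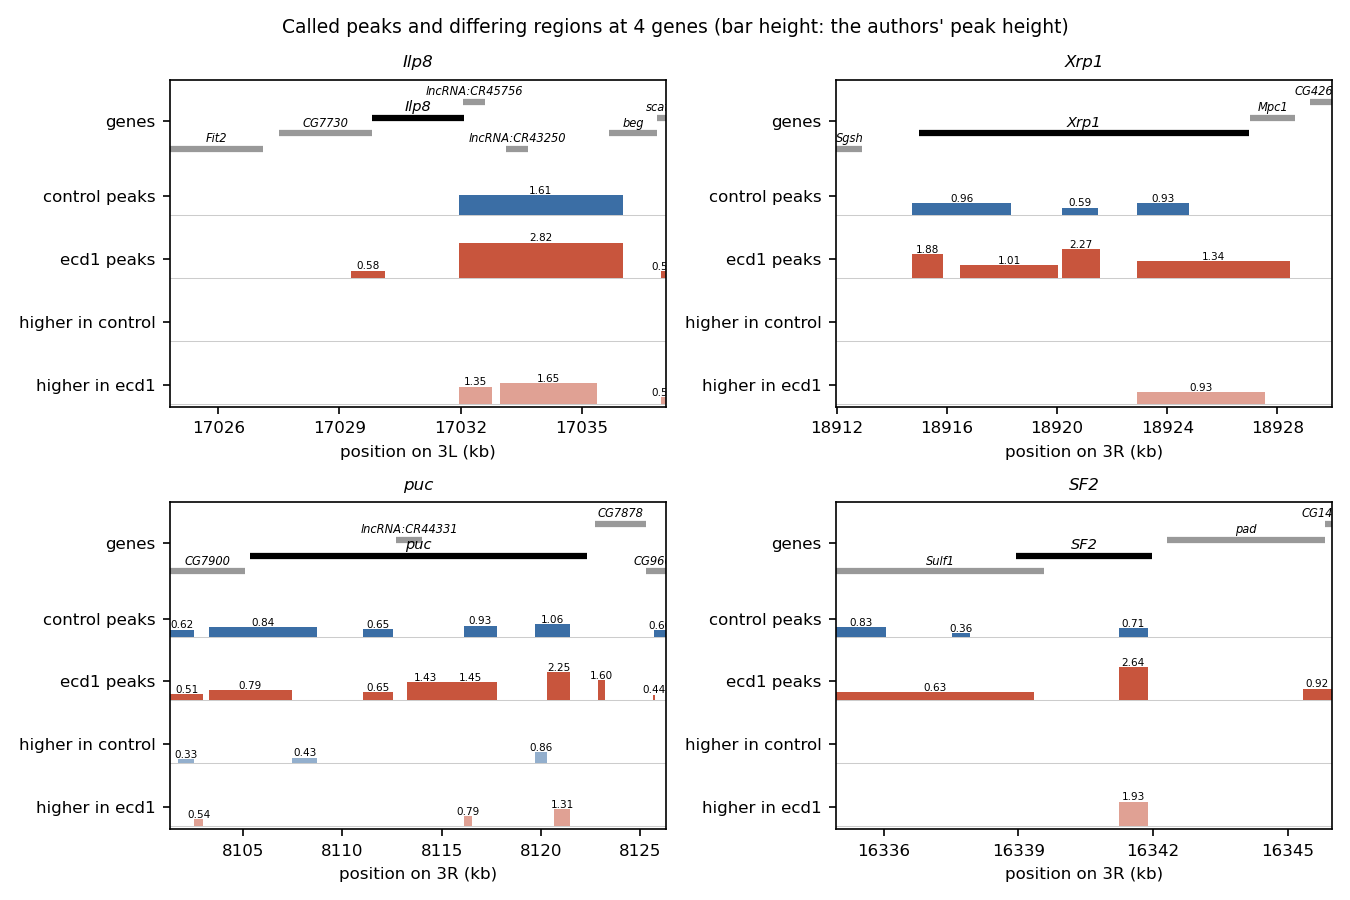
Maps of *Ilp8*, *Xrp1*, *puc* and *SF2* with their surroundings, position in kb on the x axis. From top to bottom the tracks are annotated gene spans (the named gene in black), control peaks, ecd1 peaks, and regions higher in control and in ecd1; the height of each bar is the authors' peak height, printed above it, which at *SF2* was 0.71 in control and 2.64 in ecd1.

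Gene groups were compared among the 9826 genes with a peak in either genotype, of which 57.1% had a region higher in ecd1 and 22.1% a region higher in control. The list of JNK signalling and cell death genes stood out with 28 of 30 members bearing a region higher in ecd1 (93.3%, odds ratio 10.6, two-sided Fisher exact test, adjusted p = 0.000147 over the 38 tests). The fixed list was broader than its name. It also held *upd1*, *upd2*, *upd3*, *hop*, *dome*, *Stat92E* and *Socs36E*, genes of cytokine signalling, and *chinmo*, *ftz-f1*, *moi* and *Timp*. Over 6 alternatives the odds ratio was lower, from 5.69 among the regions of larger height to 8.36, and past the threshold in each. The members included the kinase genes *bsk* and *hep*, the ligand and receptor genes *egr*, *grnd* and *wgn*, the caspase genes *Dronc* and *Dcp-1*, *Mmp1*, and the cytokine genes *upd1*, *upd2* and *upd3*. In the authors' deposited table *ftz-f1* had a region of 1.51 (3L:18786998-18787552) and *chinmo*, a transcription factor gene, one of 1.39 (2L:1667629-1668152). Next to the latter, also inside *chinmo*, the authors' deposited table gives a region of 1.21 higher in control (2L:1666232-1667629). Regions higher in control were listed for 6 of the 30, where the share among all genes was 22.1% (odds ratio 0.88, Fisher exact test, adjusted p = 1). One of these 6 was the cell death gene *hid*, which had no region higher in ecd1; *rpr* had neither.

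Wing patterning genes carried differing regions in both directions. Of 67 members with a peak, 63 had a region higher in ecd1 (odds ratio 11.97, Fisher exact test, adjusted p = 7.06e-10) and 38 a region higher in control (odds ratio 4.67, adjusted p = 1.48e-08), with 36 in both sets. Over 6 alternatives the odds ratio ranged from 4.40, with gene length and number of peaks in the model, to 13.7 on the ecd1 side, and from 1.92 to 6.86 on the control side. Besides *N* and *emc*, the authors' deposited table gives 1.67 for *fz3*, a Wnt receptor gene (X:769092-769902), and 1.65 for *brk*, the repressor of Dpp targets, from a region 4744 bp away (X:7301608-7303195). The control-side call was lost among the regions of larger height (odds ratio 2.21, Fisher exact test, adjusted p = 0.0534). It was also lost with gene length and number of peaks in a logistic model, where the odds ratio was 1.92 (95% interval 1.15 to 3.20 before adjustment over the lists).

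Ecdysone response genes had a region higher in ecd1 in 24 of 28 cases (odds ratio 4.53, Fisher exact test, adjusted p = 0.00855) and higher in control in 11 (adjusted p = 0.146). The authors' deposited table gives 1.79 for *br* (X:1612881-1613899), 1.42 for *Eip75B* (3L:18013141-18014191), 1.39 for *EcR*, the receptor gene (2R:6148008-6150567), and 1.36 for *Eip78C* (3L:21253804-21254484), all inside the genes. The ecdysone call was lost with gene length in the model, at an odds ratio of 2.49 (95% interval 0.84 to 7.35), and with genes reassigned by their annotated spans (odds ratio 2.10, Fisher exact test, adjusted p = 0.226).

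Ribosomal protein genes had a region higher in ecd1 less often than other genes with a peak, in 21 of 70 cases (30%, odds ratio 0.32, Fisher exact test, adjusted p = 6.36e-05), and a region higher in control in 15 (odds ratio 0.96, adjusted p = 1). In the authors' deposited tables *RpS30* (1.17), *RpL8* (1.10) and *RpLP0* (1.08) had regions higher in ecd1 and *RpS20* one of 1.25 higher in control, 216 bp outside the gene. With genes reassigned by their annotated spans, the odds ratio was 0.53 (Fisher exact test, adjusted p = 0.0557).

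Genes of small RNAs also had a region higher in ecd1 less often: 53 of 138 snRNA and snoRNA genes (odds ratio 0.46, Fisher exact test, adjusted p = 0.000114) and 61 of 148 tRNA genes (odds ratio 0.52, adjusted p = 0.000678). On the control side the counts were 14 (odds ratio 0.39, Fisher exact test, adjusted p = 0.00211) and 30 (odds ratio 0.89, adjusted p = 0.823). The tRNA call on the ecd1 side was lost among genes with a peak in both genotypes (odds ratio 0.59, Fisher exact test, adjusted p = 0.0534), and the snRNA and snoRNA call on the control side with reassignment by span (0.59, adjusted p = 0.0586). With only the nearest gene of each region the snRNA and snoRNA ratios were 0.15 and 0.13. These genes are short, and with gene length in the model the directions turned to odds ratios of 1.07 (95% interval 0.72 to 1.57) and 1.57 (1.11 to 2.23) on the ecd1 side, neither past the threshold after adjustment. On the control side that model gave 1.05 for snRNA and snoRNA genes and called tRNA genes more often than others (odds ratio 2.92, 95% interval 1.90 to 4.5).

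The remaining lists did not pass the Fisher exact test in either direction, with adjusted p from 0.135 upward. Spliceosome genes had a region higher in ecd1 in 16 of 29 cases and higher in control in 3. Examples from the authors' deposited table are 1.93 for *SF2*, an SR splicing factor gene (3R:16341237-16341885), and 1.49 for *SmB*, a core snRNP gene (2L:10425250-10426120). For Xrp1 and stress genes the counts were 17 and 6 of 24; the authors' deposited table gives 1.72 for a region 800 bp from *GstD2* and 1017 bp from *GstD1*, detoxification genes, 1.45 for *Sesn* and 1.42 for *Ire1*, a sensor of protein folding. Hippo and growth genes counted 19 and 8 of 25, with 1.64 for *foxo* and 1.47 for *Max* in the authors' deposited table. DNA damage genes counted 17 and 2 of 24, cell cycle and replication genes 15 and 10 of 31, Polycomb and Trithorax genes 11 and 7 of 17, R-loop factors 6 and 3 of 16, and heat shock genes 7 and 2 of 13. Among markers of other cells that a wing disc preparation can hold, myoblast and muscle genes counted 12 and 6 of 14 (Fisher exact test, adjusted p = 0.135 and 0.286), neuron and glia genes 8 and 5 of 16, and genes of trachea, blood cells and fat body 8 and 5 of 13. With only the nearest gene of each region, myoblast and muscle genes passed in both directions (odds ratios 5.80 and 4.35, Fisher exact test, adjusted p = 0.0166 and 0.0400). The Dam constructs were expressed under the wing driver *nub*, so the counts of these marker lists do not measure the content of other cells. Genes present in the transgenes counted 4 and 0 of 5. The only histone gene with a peak had no differing region.

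**Figure D3:**
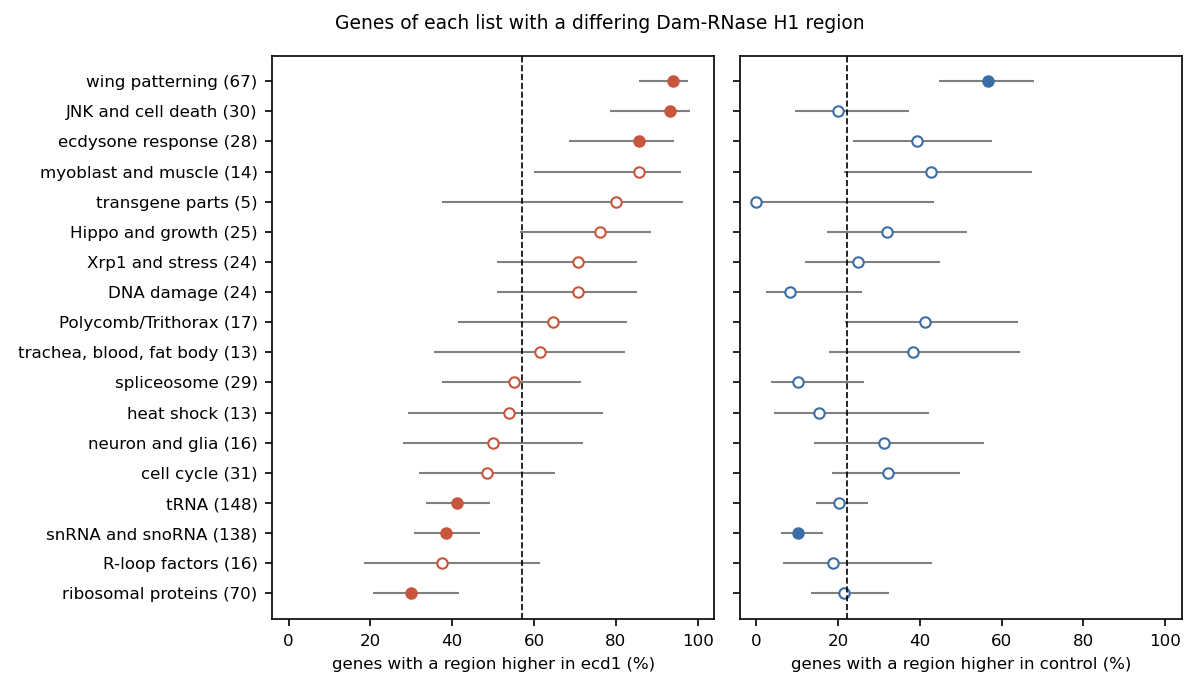
Share of the genes of each list with a region higher in ecd1 (left) and higher in control (right), in percent of the members with a peak in either genotype, whose number stands in brackets. Bars are 95% Wilson intervals (counting error only), dashed lines the share among all 9826 genes (57.1% and 22.1%), and filled points lists past an adjusted p of 0.05; JNK and cell death genes reached 93.3% on the left and 20% on the right.

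The directions were also compared with each other, among genes with regions in 1 direction only. Ribosomal protein genes were the only list past the threshold. They numbered 19 with ecd1-higher and 13 with control-higher regions (odds ratio 0.32, Fisher exact test, adjusted p = 0.0398 over 18 lists). This call was lost among the regions of larger height (Fisher exact test, adjusted p = 0.114) and with the nearest gene of each region (adjusted p = 0.438). JNK and cell death genes numbered 23 against 1 (odds ratio 5.06, Fisher exact test, adjusted p = 0.476) and wing patterning genes 27 against 2 (odds ratio 2.97, adjusted p = 0.530), so their shares were not shown to differ between directions. Spliceosome and ecdysone genes both numbered 15 against 2, which did not pass either.

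Several lists had a peak more often than annotated genes in general. Of all annotated genes, 46.6% had a listed peak in control and 49.2% in ecd1. Wing patterning genes had one in 66 and 67 of 70 cases (Fisher exact test, adjusted p = 1.71e-16 and 2.02e-16), JNK and cell death genes in 30 of 36 in each genotype, ecdysone genes in 24 and 25 of 29, Hippo and growth genes in 23 of 28 in each, cell cycle genes in 29 and 27 of 36, ribosomal protein genes in 59 and 56 of 87, and Xrp1 and stress genes in 23 and 22 of 31. Each of these passed in both genotypes, with adjusted p at or below 0.0352. Gene length in the model lowered the odds ratios of all these lists but ribosomal protein genes. Those of wing patterning genes fell from 19.1 (control) and 23.2 (ecd1) to 8.87 and 10.1. Those of ecdysone genes fell from 5.52 and 6.46 to 2.84 and 3.18. In ecd1, however, the calls of Xrp1 and stress genes and of ribosomal protein genes were lost among protein-coding genes only (Fisher exact test, adjusted p = 0.0937 and 0.0697), and that of Xrp1 and stress genes also with gene length in the model (odds ratio 1.99). Myoblast and muscle genes passed in ecd1 (14 of 18, Fisher exact test, adjusted p = 0.0352) and not in control (13 of 18, adjusted p = 0.0609); the genotypes were not tested against each other. The ecd1 call was lost in all 3 alternatives run, namely protein-coding genes only and reassignment by span (Fisher exact test, adjusted p = 0.0729 and 0.101) and gene length in the model (odds ratio 1.497). Spliceosome genes had a peak in 20 and 26 of 51 cases and did not pass (Fisher exact test, adjusted p = 0.428 and 0.965). Nor did DNA damage genes (19 and 22 of 33), Polycomb and Trithorax genes (14 and 15 of 22), R-loop factors (15 and 13 of 25), heat shock genes (12 of 24 in each), neuron and glia genes (13 and 14 of 23), genes of trachea, blood cells and fat body (10 and 12 of 24), and transgene parts (5 and 4 of 10). Histone genes, which lie in a repeated cluster, had a peak in 1 of 112 cases. Peaks were listed for 93 and 103 of 306 snRNA and snoRNA genes (odds ratios 0.50 and 0.52) and 123 and 121 of 295 tRNA genes (0.82 and 0.71; Fisher exact test, adjusted p = 0.157 and 0.0106). With gene length in the model the snRNA and snoRNA ratios turned to 1.47 and 1.70 and the tRNA ratios to 3.14 and 3.03. All of these passed in the opposite direction (likelihood ratio test of the logistic model, adjusted p at or below 0.0105).

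Peaks lay near the ends of genes more often than chance placement gave. Peak midpoints fell within 500 bp of either end of an annotated gene for 32.6% of control and 31.5% of ecd1 peaks, against 18.1% on average in shuffled placements for both (two-sided permutation p = 0.002, the smallest the 1000 placements can give). For regions higher in control the share was 36.5% and for regions higher in ecd1 38.7%, both against 18.1% (permutation p = 0.002). Differing regions were deposited only where assigned to a gene, but they were shuffled along whole arms. Part of their excess at gene ends and inside spans is fixed by that format. Their shares can therefore not be compared with those of the full peak lists. Midpoints lay inside a gene span for 71.7% of control peaks, 75.2% of ecd1 peaks, 72.5% of regions higher in control and 80.1% of regions higher in ecd1, where the means of the shuffled placements were 69.9% to 70.2%. The shares of ecd1 peaks and of regions higher in ecd1 lay above every placement (permutation p = 0.002 for each). Those of control peaks and of regions higher in control lay within the range of the placements, which reached 71.96% and 73.1% (permutation p = 0.008 and 0.022). Strand and exons are not in the annotation used, so starts and ends of transcription were not separated.

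Peak density was similar on all chromosome arms. Control peaks numbered from 61.2 per Mb on 3R to 67.8 per Mb on X, and ecd1 peaks from 70.1 on 2L to 76.0 on X. The share of differing regions higher in ecd1 was 73.3% on X, and 68.9% on 2L, 71.3% on 2R, 70.7% on 3L and 72.2% on 3R; all 25 differing regions of chromosome 4 were higher in ecd1. X held 725 regions higher in ecd1 and 264 higher in control, which did not differ from the autosomes by the two-sided Fisher exact test (odds ratio 1.12, p = 0.175).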

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

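Reassignment of genes by span, circular shifts, the model with number of peaks and the alternatives of the direct comparison were chosen after seeing the data. Over all results and lists 146 alternative values were computed, of which 100 kept their direction and side of the threshold (or lay within the interval or 1.5 times the count). The cause of the other changes was not tested. The share of differing regions higher in ecd1, 71.5%, was 86.8% in the regions above the median height and 92.2% at heights of at least 1. It was 73.6% at an FDR under 0.001 and 74.4% on called peaks, so it lay higher in each of these. Regions higher in ecd1 had the larger heights (median 0.74 against 0.52). The rise with the filters on height therefore follows from the heights and adds no support for the excess. With regions within 1000 bp merged it was 71.3%. Overlap fell by construction with a reciprocal overlap of 50%, to 63.9% of control and 57.5% of ecd1 peaks; at an FDR under 0.001 it was 75.3% and 78.2%. Genes shared with ecd1 were 79.4% of the control genes at that FDR and 80.2% among genes overlapping their peak, against 87.1%. The fold over shuffled placement ranged from 3.41 to 3.50. Of the 6 lists called on the ecd1 side, gene length in the model left 3, with or without the number of peaks. On the control side, where 2 lists were called, 1 list was called in each of 3 alternatives. It was snRNA and snoRNA genes with the regions above the median height and wing patterning genes with reassignment by span. With gene length and number of peaks it was tRNA genes, which were not among the 2. The count of 2 with gene length alone was wing patterning and tRNA genes. The direct comparison called 0 lists instead of 1 with the regions above the median height and with the nearest gene of each region, where ribosomal proteins had unadjusted p of 0.0127 and 0.0384. Among lists with a peak in ecd1, 6 instead of 11 were called for protein-coding genes only. The lists of snRNA and snoRNA and of tRNA genes drop out there by construction, and ribosomal proteins, Xrp1 and stress, and myoblast and muscle genes lost their calls (Fisher exact test, adjusted p = 0.0697, 0.0937 and 0.0729). The direction turned for the short RNA genes. With gene length in the model the odds ratio was 1.07 for snRNA and snoRNA and 1.57 for tRNA genes on the ecd1 side (1.13 for tRNA with the number of peaks added) and 1.05 for snRNA and snoRNA genes on the control side. Among genes with a peak, gene length gave 1.47 (control) and 1.70 (ecd1) for snRNA and snoRNA genes, past the threshold. For tRNA genes in ecd1 it gave 3.03, also past the threshold. Reassignment by span gave 1.01 for snRNA and snoRNA genes in control and 1.05 for tRNA genes in ecd1, neither past it. The call of JNK and cell death genes on the ecd1 side held in each of the 6 alternatives (odds ratios 5.69 to 8.36), as did that of wing patterning genes (4.40 to 13.7). No paired analysis was possible because the files carry no value of a single library. For the same reason leaving out replicates, another normalisation and a filter on low signal were not run, and base content and GATC density were not run without a genome sequence. The depth of the libraries is unknown, so what it limits cannot be given.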

Other observations

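Peaks found in 1 genotype only were low, with a median height of 0.63 for 1416 control peaks without ecd1 overlap (0.88 for all control peaks) and 0.74 for 2218 ecd1 peaks without control overlap (1.10 for all ecd1 peaks). Only 31.2% of these control peaks and 45.4% of these ecd1 peaks overlapped a region the authors give as higher in that genotype. Such regions are limited to 1 per gene and direction, so the other peaks are not shown to be equal. Among the 15 tallest ecd1-only peaks beside a gene, singled out after their values were seen, were those at *borr*, a gene of the chromosomal passenger complex (2L:9252033-9252723, 2.22, the tallest), *GCS2alpha*, a glucosidase subunit gene (X:21598795-21599324, 2.16), *Ns3*, a nucleostemin family gene (X:1462327-1463413, 2.10), *SmB* with *CG5168* (2L:10425250-10426120, 1.98) and *rin*, the G3BP homologue (3R:13647152-13648945, 1.86). Among the 15 tallest control-only peaks the first 4 were those at *Desat1*, a fatty acid desaturase gene (3R:12442750-12444857, 1.69), *Srp19* with *qm* and *CR45833* (3L:7347414-7348977, 1.60), *GC1* with *CG12213* (3R:11966845-11968702, 1.57) and *tRNA:Val-CAC-1-1* (3R:17615451-17617429, 1.55). Genes listed with a peak in 1 genotype only included 9 spliceosome genes for ecd1, among them *Prp31*, *Prp8*, *SmB* and *mago*. For control they included 3, *Prp38*, *SC35* and *sqd*. These counts did not pass the Fisher exact test (odds ratio 2.09, adjusted p = 1), and so few genes cannot show that the shares are equal. A listing in 1 genotype is also not the absence of a peak in the other, as a control peak lay 714 bp outside *Prp8*.

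Of the tests below, those on the signal range, the logistic models with the number of peaks and the comparison of models with and without peak height among the same genes were chosen after seeing the data. More regions were higher in ecd1 than in control, 4083 against 1628. A candidate technical explanation is the same profile with a larger signal range in ecd1. It stays open for both directions. Regions higher in control overlapped control peaks in 76.4% of cases, against 18.3% in shuffled placements, but they were selected for control signal and the noise between libraries is unknown. The prediction that a high share would speak against a larger range was therefore wrong, and the test excludes nothing. The share of control peak bases in regions higher in ecd1 was 17.3% in the tallest of 10 groups of control peaks and 9.78% in the lowest, a ratio of 1.77, as a larger range would give, and the single Dam-only library of each genotype was not tested. A wider formation of RNA:DNA hybrids after loss of ecd1 function, the difference the design names, was not tested against it.

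JNK and cell death genes had a region higher in ecd1 in 28 of 30 cases. Their median length was 8240 bp against 2242 bp for all genes with a peak, so longer genes could account for the count. In logistic models the odds ratio was 7.73 (95% interval 1.83 to 32.6) with gene length, 8.01 (1.88 to 34.1) with the height of the control peak added, and 6.18 (1.45 to 26.3) with the number of called peaks added, so none of the 3 removed it. A larger signal range in ecd1 would act through tall control peaks. Among the 8237 genes with a control peak, 1 unit of its height raised the odds of a region higher in ecd1 by a factor of 2.53 (2.24 to 2.86), yet adding it took the odds ratio of the list only from 8.21 to 8.01. The height of the listed control peak thus did not account for the odds ratio of the list. Only the 1 listed peak of each gene entered, which need not lie under the differing region, so the model cannot exclude a larger range. A larger range as the whole cause or as part of it stays open. No biological explanation was tested, and the direct comparison of the directions (Fisher exact test, adjusted p = 0.476) did not separate them.

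Wing patterning genes had regions in both directions in 36 of 67 cases, against 12.3% of all genes with a peak. Their median length was 19487 bp. The odds ratio for both directions was 8.47 with no covariate. It fell to 3.50 (95% interval 2.10 to 5.82) with gene length in the model and to 1.85 (1.07 to 3.22) with the number of peaks added. Most of the excess thus went with length and peak number, and what was left had a lower bound close to 1. No biological explanation was tested.

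It was expected that neighbouring differing regions would share their direction. Of 5705 neighbouring pairs, 54.9% did, fewer than the 57.7% to 61.2% of 1000 permutations within arms. The tables keep 1 region per gene and direction, which spaces regions of the same direction apart, so this test decides nothing.

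Chromosome 4, chosen after its counts were seen, held 25 regions higher in ecd1 and 0 higher in control; no test is given, as the arm was picked for this count. Of the control peaks 3572 (41.5%) and of the ecd1 peaks 4105 (42.9%) are not the listed peak of any gene. The gene tables hold 1 peak per gene, so further peaks of a listed gene can fall among them. These peaks therefore need not lie away from genes. Their median heights were 0.81 (control) and 1.01 (ecd1), and 80.4% and 73.7% of them overlapped a peak of the other genotype. Genes listed with a peak in neither genotype but with a differing region numbered 674. Of these, 411 (61.0%) had a region higher in ecd1 and 281 (41.7%) one higher in control. They need not lack a peak. Within 1000 bp of a control peak lay 1457 genes not listed for control, and within 1000 bp of an ecd1 peak 1433 not listed for ecd1.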
